A study of Mus musculus with 4 samples.

How the data were processed

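ChIP-seq libraries were made from sorted pro-B cells of wild-type mice. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication and immunoprecipitation used a commercial magnetic bead kit. Groups were taken from the antibody named in the labels, with 2 libraries for anti-IgD and 2 for mouse IgG, and replicate numbers from the sample titles. The submitters' processing notes name HISAT2, MACS2 and ChIPseeker and the genome build mm10, without versions or settings, so the duplicate filter, the handling of reads that map to several places and any list of excluded regions are not given in the sources used here. The labels tie 1 peak list to each IgD library and the IgG library of the same number.

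Each deposited list has the 10 columns of the narrowPeak format. The fold enrichment at the summit (a ratio of IgD fragments to the local background), the -log10 p and the -log10 q were deposited by the authors as their peak caller gave them. The integer score of each peak, also deposited, was not used. The lowest -log10 q was 1.31 in pair 1 and 1.30 in pair 2, so both lists end at a q just under 0.05. No rows overlapped within a list. Total reads per library were not used here. The number of fragments at each summit was solved from the fold, taken as (fragments + 1) / (background + 1), and from the p-value, taken as the upper tail of a Poisson distribution. This assumes that the IgD fragments were not scaled, which the sources used here do not state. All peaks of both lists had a solution within 0.01 of their deposited -log10 p. Fragment intervals are exact Poisson intervals at 95% and cover counting error only. Shares have 95% Wilson intervals.

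Gene positions came from a table of NCBI RefSeq genes on GRCm38, the assembly that mm10 names. The table lists no strand, exons or sequence. In it, 348 genes whose coordinates belong to scaffolds outside the assembled chromosomes were left out, which left 49595 genes, 21774 of them protein-coding. The design had fixed a window of 3000 bp around gene starts. As strand was lacking, the window was set around either annotated end of a gene, so end regions of genes are counted together with promoters. No genome sequence was used, and results on motifs, repeats and GC content were not run. Gene lists were fixed before the data were examined. Of the 270 genes given by name in lists of 60 or fewer, 256 matched a protein-coding gene in the table, and the 12 immunoglobulin constant region genes, which the table puts in another class, were counted apart. That left 14 lists for the test.

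Peaks were shared when they overlapped by at least 1 bp. Overlap was tested against 1000 random placements of pair 1 peaks on the same chromosome with their widths kept, between the outermost peaks or genes of that chromosome. Assembly gaps and sequence where reads cannot be mapped were not excluded from random placements or random positions, as no genome sequence was used. Added after the data were seen were rotation of all peaks of a chromosome by a common step, moves of each peak by 20 to 100 kb or 2 to 10 kb, and limits on width of 2000 and 5000 bp. Summits near gene ends and inside genes were tested against random positions (permutation tests, two-sided). Gene lists were tested with Fisher's exact test against all other protein-coding genes with Benjamini-Hochberg adjustment over the 14 lists. This test takes no account of gene length or of clustering along the chromosome. Correlations of fold used 100000 resamples. Genes named in the text were, by a rule set before the data were examined, E2f3, Ighd and Ighm, the first 25 genes by mean rank of fold among those with a summit within 3000 bp in both lists, and members of lists of 60 genes or fewer with a summit in both lists. One gene that this rule names is not reported here. Alternatives set beforehand were stricter q and fold thresholds, 50% reciprocal overlap, summits within 200 bp, equal list lengths, placement near gene ends, a 1000 bp window and each pair alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

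The procedures were tested on simulated data. Of 20 unrelated pairs of lists with the widths of the narrow peaks, 1 had an overlap p under 0.05. With 927 of 9271 narrow peaks copied from the other list, an excess of 900 was found over random placement and of 904 over local moves, and 21.1% of the overlap was left after a move of 5000 bp. Of 200 random sets of genes, 3 had a Fisher p under 0.05, and in a list where 50% of genes were given a summit 55.5% had one, including the background. Here every gene had the same independent background probability of a summit. The simulation therefore does not show how the list test behaves with clustered genes or genes of unlike length. Fragment counts were recovered in 300 of 300 simulated summits.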

Results

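Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on pro-B cells, the bone marrow stage of B cell development that precedes surface IgM, sorted from wild-type mice as cells positive for B220 and CD43 and negative for IgM. An antibody against IgD, the immunoglobulin class best known from the surface of mature naive B cells, was used in 2 libraries, and mouse IgG served as the isotype control in the other 2. The series title asks whether IgD in the nucleus of pro-B cells acts on E2f3, a transcription factor of cell cycle entry. Each IgD library was compared with the IgG library of the same number, which gave 2 peak lists, called pair 1 and pair 2 here. With 1 list per pair and no list of IgG peaks, the agreement between the pairs was the replicate check, and a difference between IgD and IgG could be read at called peaks only. The labels do not say whether the pairs came from separate mice. P-values below compare peak positions with random positions, genes of a list with other genes, peaks of a list with each other, or folds across peaks, and none measures a spread between animals.

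Pair 1 held 11375 peaks and pair 2 held 40628, a ratio of 3.57. Of these, 1873 peaks in pair 1 (16.5%) and 15745 in pair 2 (38.8%) had a -log10 q of at least 5. The median peak was 856 bp wide in pair 1 and 774 bp in pair 2, with a median fold enrichment of 3.46 and 3.78. Few fragments stood behind a typical peak, by numbers solved from the fold and the p-value on the assumption that the peak caller added 1 and did not scale the IgD fragments. Its settings are not known, and with scaling these numbers would not be counts and their Poisson intervals, here and below, would not hold. The median summit in pair 1 solved to 13 IgD fragments (95% exact Poisson interval 6.92 to 22.2, counting error only) and the commonest background level was 2.756 fragments. In pair 2 the corresponding values were 14 fragments (7.65 to 23.5) and 2.699. On that scale, 1 fragment more or less moved the fold of such a peak by 0.266 in pair 1 and by 0.270 in pair 2. Very wide peaks took most of the covered sequence. In pair 1, 1083 peaks of 5000 bp or wider held 74.9% of the 44.2 Mb covered, and in pair 2, 1295 such peaks held 54.8% of 75.5 Mb.

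E2f3 (chromosome 13, 29906575 to 29986064, mm10) carried an IgD peak in pair 2 and none in pair 1. The pair 2 peak spanned 29984222 to 29984747, with its summit at 29984427, inside the gene and 1637 bp from its higher-coordinate end. Its fold was 5.57 and its -log10 q 14.1, from 34 fragments at the summit (95% exact Poisson interval 23.5 to 47.5) over a background of 5.29. It ranked 984 by q among the peaks of pair 2, in the top 2.42%. In pair 2, 3652 protein-coding genes (16.8% of all) had a summit within 3000 bp of either end. Of these, 490 had a higher fold than E2f3. The nearest pair 1 peak to E2f3 lay 621 kb away. Within 200 kb on either side of the gene, pair 2 had 8 peaks, 1 of them at E2f3, with folds up to 5.57, and pair 1 had 0. Over the whole of chromosome 13, pair 2 had 15.3 peaks per Mb and pair 1 had 3.40. Whether this window held more or fewer peaks than those densities give was not tested. The table of genes gives neither strand nor exons, so which end of E2f3 is its transcription start, and whether the summit is exonic, were not assigned.

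**Figure D1:**
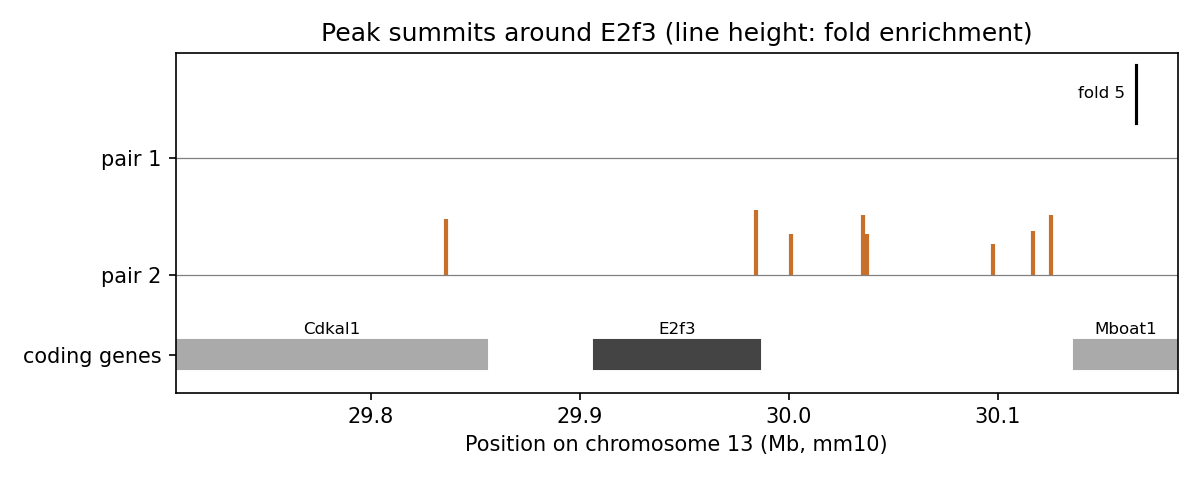
Peak summits on chromosome 13 from 200 kb below to 200 kb above E2f3 (x axis, position in Mb, mm10), with line height showing fold enrichment against the scale bar of fold 5 and boxes showing protein-coding genes. Pair 2 has 8 summits in the window, 1 of them inside E2f3 at fold 5.57, and pair 1 has 0. Over the whole of chromosome 13, pair 2 has 15.3 peaks per Mb and pair 1 has 3.40.

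The genes for the IgD and IgM heavy chains were free of called peaks. No peak of either list lay within 10000 bp of Ighd (chromosome 12, 113407535 to 113416324) or of Ighm (113418826 to 113422730). The nearest peaks to Ighd were 241 kb away in pair 1 and 31.8 kb away in pair 2. Among 12 immunoglobulin constant region genes, 0 had a summit within 3000 bp of an end in pair 1 and 2 did in pair 2, Ighe and Ighg1.

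The other E2F genes were next compared between the pairs. In pair 2, 4 of 13 E2F family members and partners had a summit within 3000 bp of an end. Besides E2f3 these were E2f1, an activator E2F (fold 8.03), E2f5 (fold 3.51) and Tfdp1, a dimerisation partner of the E2Fs (fold 4.83). This was 30.8% of the family against 16.8% of other protein-coding genes (odds ratio 2.21, Fisher's exact test, two-sided, p = 0.253, Benjamini-Hochberg adjusted p = 0.884 over 14 lists). In pair 1, 0 of the 13 had one, against 2.87% of other genes. E2F targets and DNA replication genes had a summit in 7 of 47 cases in pair 2, among them Ccne1, which encodes cyclin E1 (fold 6.06), Rfc3 (fold 5.14) and Rpa1 (fold 5.25), the highest folds of the 7. This was 14.9% of the list against 16.8% of other genes (odds ratio 0.868, Fisher's exact test, adjusted p = 0.912). Pair 1 had 1 of 47, Uhrf1 (fold 2.96; adjusted p = 1, Fisher's exact test). These genes, apart from E2f3, were chosen for naming after their values were seen, because no member of a list of 60 genes or fewer had a summit in both pairs.

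No cell cycle or B-lineage list passed the same test. In pair 2, summits lay near 2 of 18 G1 regulators, 6 of 30 genes of G2 and mitosis, 5 of 26 early B-lineage transcription factors, 6 of 32 pro-B surface and signalling genes and 3 of 16 genes of V(D)J recombination. The adjusted p was 0.912 for each of these lists. In pair 1 the counts were 0, 2, 0, 1 and 0, with adjusted p of 0.989 for G2 and mitosis and 1 for the others. Ribosomal protein genes had 8 of 80 and histone genes 11 of 77 in pair 2 (Fisher's exact test, adjusted p = 0.616 and 0.912), against 1 and 0 in pair 1 (adjusted p = 1 and 0.989). Markers of other cell types, most of which the gate on B220 and CD43 would remove, and neural genes were counted in the same way. In pair 2, 7 of 20 myeloid genes had a summit, including Lyz2, Mpo and Ctsg, 35.0% against 16.8% of other genes (odds ratio 2.68, Fisher's exact test, p = 0.0636, adjusted p = 0.445). T cell markers had 5 of 20, erythroid markers 2 of 14 and neural genes 2 of 20 (Fisher's exact test, adjusted p = 0.912, 1 and 0.912). In pair 1 these 4 lists had 0, 1, 0 and 1 (Fisher's exact test, adjusted p = 1).

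Olfactory receptor genes, which encode the odorant receptors of the nose, passed the list test at peaks shared by the pairs only when counted as independent genes. Of 1105 such genes, 18 (1.63%) had a shared summit near an end, against 0.600% of other genes (odds ratio 2.74, Fisher's exact test, adjusted p = 0.0044). They lie in clusters, and with all peaks rotated together along their chromosomes, which keeps the clustering, the call was lost: the 18 genes compared with 8.58 ± 7.38 (SD, 1000 rotations, permutation test, two-sided, p = 0.274, adjusted p = 1). Fisher's exact test on the single lists ignores the clustering too, and it does not adjust for gene length. The windows around both ends of a short gene overlap, so a short gene offers less sequence to summits. Rotation keeps the windows of each gene. Within the single lists, 47 olfactory receptor genes had a summit in pair 1 (4.25% against 2.79%, odds ratio 1.55, Fisher's exact test, adjusted p = 0.0983), and 145 did in pair 2 (13.1% against 17.0%, odds ratio 0.739, adjusted p = 0.0097). Over genes near a summit of only 1 list, the odds of being an olfactory receptor were 1.97 times higher in pair 1 than in pair 2 (Fisher's exact test, two-sided, p = 0.0023, again without regard to clustering). Against rotation both single lists lay above the mean, pair 2 included, without passing the test: 47 genes compared with 27.3 ± 13.6 in pair 1 (permutation p = 0.208) and 145 with 122.1 ± 15.4 in pair 2 (permutation p = 0.178). The pair 2 odds ratio below 1 therefore does not by itself show that these genes were depleted. At a -log10 q of at least 5 in both lists the odds ratio was 1.07 (Fisher's exact test, adjusted p = 1).

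The lists overlapped more than random lists would. Of the pair 1 peaks, 3125 (27.5%) overlapped a pair 2 peak by at least 1 bp, and 2747 pair 2 peaks (6.76%) overlapped a pair 1 peak. Random placement on the same chromosomes gave 718 ± 24.5 (SD, 1000 placements), so the overlap was 4.35 times the random value (permutation test, one-sided, p = 0.0010, the smallest that 1000 placements can give). The overlapping share of pair 1 rose from 13.7% of peaks under 600 bp (95% Wilson interval 12.4 to 15.2) to 88.4% of those of 20000 bp or wider (84.2 to 91.6), but a wider peak also overlaps more often by chance. With widths kept, peaks of 5000 bp or wider in both lists overlapped 476 times against 34.3 ± 5.45 at random, and peaks narrower than 2000 bp in both lists 757 times against 231 ± 14.7 (SD, 1000 placements).

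Most of this overlap was kept when peaks were moved within their region. When every pair 1 peak was moved by a random 20 to 100 kb, 2691 ± 31.4 peaks still overlapped pair 2, so the ratio fell from 4.35 to 1.16 (permutation test, one-sided, p = 0.0010). It was no higher for the wide peaks (1.15) than for the narrow ones (1.23). A move of this size can leave a wide peak on the same partner. In all, 293 pair 1 peaks and 318 pair 2 peaks were 20000 bp or wider. The ratio of wide peaks, and in part that of all peaks, therefore cannot separate region from position. Among peaks narrower than 2000 bp in both lists, 757 overlapped in place, 739 after a move of 2 kb, 717 after a move of 5 kb and 234 after a move of 500 kb, where random placement gave 231. Summits within 200 bp of each other occurred for 183 of the 9271 narrow pair 1 peaks (1.97%), against 160 ± 12.04 after moves of 2 to 10 kb (permutation test, one-sided, p = 0.0400). Moves of 20 to 100 kb gave 140 ± 11.8 for these narrow peaks (permutation test, one-sided, p = 0.0010). Over all peaks the count was 333, against 257 ± 15.7 after moves of 2 to 10 kb and 222 ± 14.8 after 20 to 100 kb (permutation test, one-sided, p = 0.0010 in both). The width limits and the local moves were chosen after seeing the data.

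**Figure D2:**
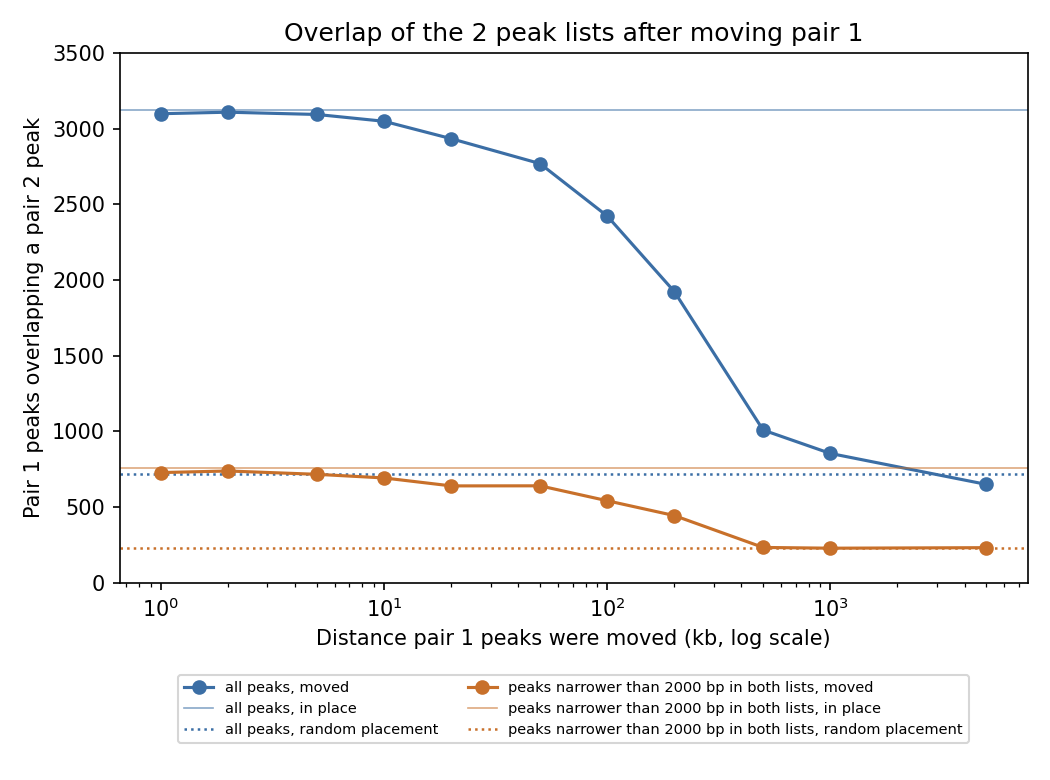
Number of pair 1 peaks overlapping a pair 2 peak (y axis) after all pair 1 peaks were moved by a fixed distance (x axis, kb, log scale, mean of both directions), for all peaks and for peaks narrower than 2000 bp, with the overlap in place (solid lines) and the mean of 1000 random placements (dotted lines). Narrow peaks overlap 757 times in place and 717 times after 5 kb, and reach the random level of 231 at about 500 kb.

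Peak strength was weakly related between the pairs. Across the 3125 overlapping peaks the folds had a Spearman's rho of 0.0301 (permutation p = 0.0930) and a Pearson's r of 0.104; these are correlations across peaks, which are not independent replicates. Over the 445 pairs that overlapped reciprocally by at least 50%, rho was 0.276 (permutation p = 1.0e-05, the smallest that 100000 resamples can give). Within these, rho was 0.352 over 188 pairs with a peak of 2000 bp or wider (permutation p = 2.0e-05) and 0.0017 over 257 pairs of narrow peaks (permutation p = 0.979), a split chosen after seeing the data and not itself tested. With an overlap of at least 1 bp, rho was 0.114 over 463 pairs both 5000 bp or wider (permutation p = 0.0140). It was -0.0192 over 750 pairs both narrower than 2000 bp (permutation p = 0.599). Reciprocal overlap selects peaks of similar width, and whether width accounts for its rho was not tested.

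Most of the strongest shared regions were long blocks. The shared region with the highest fold in pair 1 spanned chromosome 4 from 145677545 to 146052156 (375 kb, fold 23.2) and from 145647464 to 146054562 in pair 2 (fold 14.8). On chromosome 1, a block from 84995185 to 85499845 had a fold of 12.8 in pair 1 and 24.1 in pair 2. Further blocks lay on chromosome 4 from 146939045 to 147334291 (fold 11.7 and 16.8), on chromosome 14 from 41976563 to 42468540 (fold 11.98 and 8.65) and on chromosome X from 33429499 to 33810032 (fold 10.7 and 8.92). Of the 20 shared regions with the highest pair 1 fold, 18 were 5000 bp or wider in pair 1, 12 held a protein-coding gene and 8 held none. On chromosomes 1-19, X and Y lay 18 of the 20. The rest lay on other sequences, for which no gene positions were used, and are among the 8. The 793 shared peaks of that width covered 234 protein-coding genes. Among these were 16 vomeronasal receptor genes (Vmn), 14 olfactory receptor genes (Olfr), 13 Btbd35f genes, 12 zinc finger genes (Zfp), 10 Pramel genes and 6 major urinary protein genes (Mup), and 108 genes with a provisional name only.

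A summit within 3000 bp of an end in both lists was found for 211 protein-coding genes, from 624 genes in pair 1 and 3652 in pair 2. Random placement of the pair 1 summits gave 169 ± 13.2 and rotation gave 121 ± 13.5 (permutation test, one-sided, p = 0.0010 in both). Both moved summits along the whole chromosome, and local moves were not run for this count. The excess therefore cannot tell shared genes from shared regions. A pair 1 peak that overlapped a pair 2 peak had its summit near an end of 142 genes. Ranked by fold in both lists, Cxcl13, which encodes a chemokine that attracts B cells, came first (chromosome 5, 95956939 to 95961068). Its fold was 6.66 in pair 1, from 24 fragments (15.4 to 35.7), and 7.03 in pair 2, from 25 fragments (16.2 to 36.9), but the pair 1 peak was 19725 bp wide and the summits lay 4559 bp apart. Frk, a Src-family kinase gene, followed with folds of 4.79 and 7.84 from peaks that did not overlap. At Mgmt, which encodes a DNA repair protein, the folds were 4.53 and 6.76 at opposite ends of the gene, 232709 bp apart. The first 25 genes also held Gm4454, Itgbl1, Gm8126, Kif16b, LOC115486427, Gm5591, Adcyap1r1, Zfp600, A4gnt, Dok6, Otop1, Gm1979, 2410141K09Rik, Gm9507, Sec23a, Dcaf12l2, Pcdh10, BC051019, Galntl6, Gm5108 and Smok2a. Folds in this group ran from 3.99 to 6.68 in pair 1 and from 4.08 to 17.5 in pair 2. At 12 of the 25 genes the peaks overlapped, at 5 the summits were within 1000 bp, at 1 they were within 200 bp, and 13 genes had a peak of 5000 bp or wider in either list.

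Genes were under-represented at pair 1 peaks. Pair 1 summits lay inside protein-coding genes in 25.6% of cases (95% Wilson interval 24.8 to 26.4), against 38.7% for random positions on the same chromosomes (permutation test, two-sided, p = 0.0020, the smallest that 1000 placements can give). Shared peaks lay inside genes in 19.9% of cases against 38.4% at random, and pair 2 peaks in 38.3% against 40.1% (permutation p = 0.0020 in both). Rotation was not run for summits inside genes. Independent random positions ignore the clustering of peaks, so these p-values are likely too small. Within 3000 bp of an end lay 5.80% of shared summits (5.03 to 6.68) against 7.95% at random, and 6.53% of pair 1 summits against 7.98%, but 9.03% of pair 2 summits (8.76 to 9.32) against 8.22% (permutation p = 0.0020 in each). Random positions could fall in assembly gaps or unmappable sequence. The small excess in pair 2 therefore cannot be told apart from an effect of where reads can be mapped. At a window of 1000 bp the pair 1 share was 2.76% against 2.96% and its call was lost (permutation p = 0.222). For shared peaks the call was lost at a -log10 q of at least 5 in both lists (ratio to random 0.817, permutation p = 0.202), with 50% reciprocal overlap (ratio 0.744, permutation p = 0.118) and against rotation at a window of 1000 bp (ratio 0.716, permutation p = 0.0619). Against rotation at 3000 bp it was kept (ratio 0.731, permutation p = 0.0200).

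Chromosome X held an excess of peaks in pair 1. Its density there was 8.81 peaks per Mb, 2.18 times the autosomal mean (95% exact Poisson interval 2.07 to 2.29), while in pair 2 it was 0.831 times the autosomal mean (0.797 to 0.867). Poisson intervals of peak counts, here and below, treat peaks as independent. Peaks clustered by region, so these intervals are likely too narrow. At a -log10 q of at least 5 the pair 1 ratio of X was 1.35 (1.14 to 1.57), below that of chromosome 7 (1.54, 1.302 to 1.80) and close to that of chromosome 12 (1.36, 1.12 to 1.64). Pair 1 also had few peaks on chromosome 16 (ratio 0.479, 0.412 to 0.553) and more on chromosome 7 (1.43, 1.33 to 1.53), where pair 2 had ratios of 0.929 and 1.07. Chromosome Y had 98 peaks in pair 1 (ratio 0.268, 0.217 to 0.326) and 79 in pair 2 (ratio 0.0547, 0.0433 to 0.0682).

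**Figure D3:**
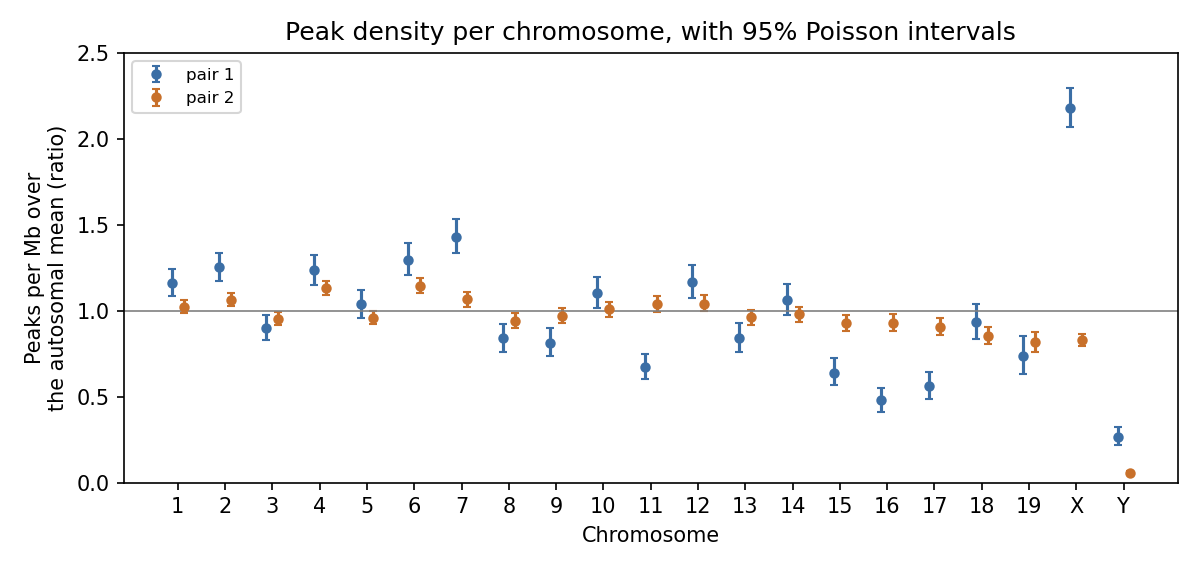
Peaks per Mb on each chromosome divided by the mean of the autosomes (y axis, ratio) for pair 1 and pair 2, with 95% exact Poisson intervals as bars. The intervals treat peaks as independent. Chromosome X stands at 2.18 in pair 1 and 0.831 in pair 2.

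**Figure D4:**
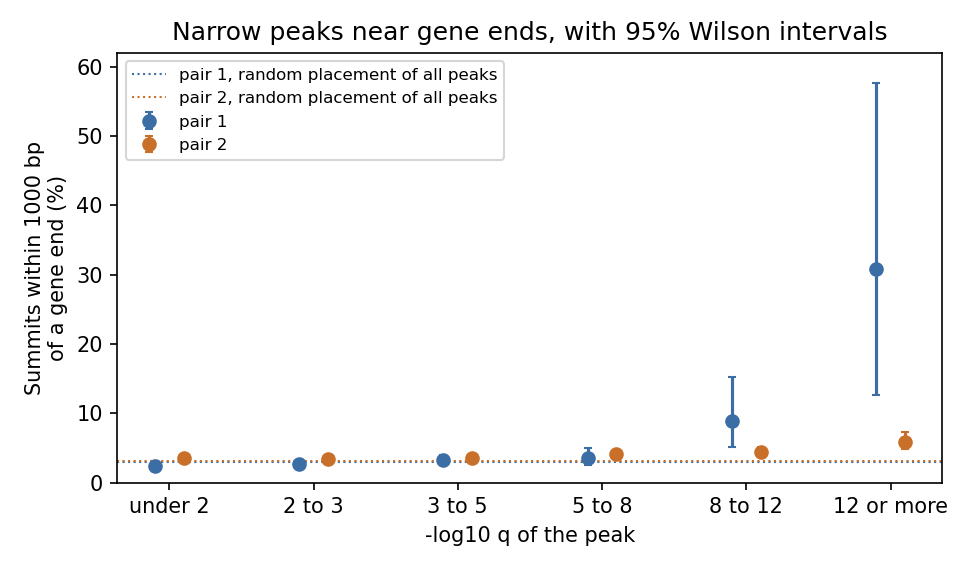
Share of summits within 1000 bp of the end of a protein-coding gene (y axis, percent) by -log10 q of the peak (x axis), for peaks narrower than 2000 bp in pair 1 and pair 2, with 95% Wilson intervals as bars and the mean of 1000 random placements of all peaks as dotted lines. In pair 1 the share is 2.38% below a -log10 q of 2 and 8.94% from 8 to 12, and the last point, 30.8%, rests on 4 of 13 peaks.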

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

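Peaks on sequences outside chromosomes 1-19, X and Y enter no gene comparison, and are listed here for that reason alone, as no expected count was available for them. Pair 1 had 90 such peaks on 9 sequences (0.791% of the list), with a highest fold of 13.4, and pair 2 had 57 on 12 sequences (0.140%), with a highest fold of 9.47. Overlap with the other pair was found for 38 of the 90 and 36 of the 57.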

How the results depend on the processing

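No paired analysis was possible because each deposited list already is the comparison of an IgD library with the IgG library of its number and holds no value per library to which a block could be fitted. Of 47 alternatives over 12 results, 28 kept the direction and the call or, for counts and untested ratios, stayed within a limit on the change. Tested results were compared by direction and call only, not by size. The overlap therefore counts as kept although its ratio fell from 4.35 to 1.16 with local moves. The overlap of the lists stayed above random under all 10 alternatives, from 1.16 times with local moves to 5.86 times with equal list lengths. The count of peaks depended on the threshold, with 1873 (pair 1) and 15745 (pair 2) at a -log10 q of at least 5 and 830 and 7776 at a fold of at least 5, which follows from removing peaks. The share of shared summits near gene ends, 0.727 times random, was 0.819 in pair 1 alone and 1.098 in pair 2 alone, the opposite direction, and 0.714 with a window of 1000 bp. Its call was lost at the stricter q (0.817) and at 50% reciprocal overlap (0.744), which left fewer peaks, and against rotation at a window of 1000 bp (0.716, permutation p = 0.0619). Lists past the test went from 1 to 0 at the stricter q and with rotation, and ranged from 0 to 1 over the single pairs. The odds ratio of olfactory receptors, 2.74, was 0.739 in pair 2 alone, the opposite direction, 1.55 in pair 1 alone, 1.07 at the stricter q and 3.91 with a window of 1000 bp; against rotation the count in pair 2 lay above the mean, not below it. The correlation of folds passed its test at 50% reciprocal overlap (0.276) and with -log10 p in place of fold (0.0402). The X ratio was 1.35 in pair 1 and 0.761 in pair 2 at the stricter q, and 0.770 in pair 2 with narrow peaks. Apart from the fall in peak counts at stricter thresholds, the causes of these changes were not tested, including whether calls were lost because fewer peaks were left. Rotation, local moves and width limits were chosen after seeing the data. Reciprocal overlap used 200 placements. The GC-matched background, the motif results and the repeat results were not run, as no genome sequence was used. What depth limits was not measured, as total reads were not used. The lowest number of fragments solved at a summit, 9 in pair 1 and 8 in pair 2, depends on the q threshold and the local background as well as on depth, so it does not show which sites, E2f3 in pair 1 included, could have been detected.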

Other observations

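The tests below were chosen after the results were seen, except those of summit distance in wide peaks and of gene density on X, whose outcomes had not been seen when their bounds were set.

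Strong narrow peaks lay near gene ends more often than weak ones. Among peaks narrower than 2000 bp in pair 1, 15 of 136 with a -log10 q of at least 8 had a summit within 1000 bp of a gene end (11.0%), against 2.82% of the 9073 weaker ones (odds ratio 4.27, Fisher's exact test, two-sided, p = 1.04e-05). Without the 13 peaks at 12 or more the share was 8.94% (odds ratio 3.38, Fisher's exact test, p = 8.73e-04). In pair 2 the shares were 4.80% of 5609 and 3.65% of 32679 (odds ratio 1.33, Fisher's exact test, p = 6.24e-05). The 4 strongest in pair 1, named after their values were seen, were at Gm45871 (chromosome 18, summit 90592934, fold 9.46), Smagp (chromosome 15, 100637076, fold 7.99), Ttc39b (chromosome 4, 83323685, fold 6.79) and Ism2 (chromosome 12, 87299588, fold 6.92). Others were at Lamp1, a lysosomal membrane protein gene (fold 5.06), Rpl38, a ribosomal protein gene (fold 5.33), and the major histocompatibility gene H2-Q6 (fold 5.18). Only at Ntan1, of the 15 sites, was there a pair 2 summit within 3000 bp.

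Among antigen receptor loci, which rearrange during B and T cell development, none of the 6 passed a test against the rest of its chromosome in either pair after adjustment over 12 tests. The immunoglobulin lambda locus (chromosome 16, 19061752 to 19260844) held 8 pair 1 summits where 0.385 were expected from the chromosome (permutation test by rotation, two-sided, p = 0.0200, adjusted p = 0.240) and 6 pair 2 summits where 2.95 were expected (adjusted p = 0.743). The heavy chain locus held 3 pair 1 summits against 12.99 expected and 55 pair 2 summits against 45.7 (permutation test, adjusted p = 1 and 0.822), and the kappa locus held 4 against 16.6 and 86 against 57.8 (adjusted p = 1 and 0.743). The 3 T cell receptor loci together gave adjusted p of 0.743 or more.

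Wide shared peaks often held gene families. Of the protein-coding genes under them, 79.1% were members of a local family or had a provisional name, against 22.8% of all protein-coding genes and at most 47.9% in 1000 rotations. Within 463 overlapping pairs of wide peaks the summits were a median of 14652 bp apart, against 14527 ± 997 bp for summits drawn at random inside the regions (permutation p = 0.553). In 12 of these pairs (2.59%) the summits lay within 200 bp. This argues against 1 strongest point shared by both pairs in most of these blocks. Each peak has only 1 summit here, so several fixed points within a block could not be excluded. Multi-copy sequence, where more copies in the mice than in the reference or shared reads would raise coverage over wide blocks, may account for them. Such copies would raise IgG as well, so a difference in yield between IgD and IgG would also be needed, and this stays open without IgG coverage.

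Overlap between the lists held up when the peaks were moved. Local moves of 20 to 100 kb left 81.5% of the overlap of narrow peaks, and a fixed move of 5 kb left 717 of 757. Isolated copied sites in the simulation left 21.1%, which argues against isolated shared sites as the whole cause. The simulated lists were not clustered by region, so shared sites that lie in clusters could not be ruled out. Regional differences in coverage between IgD and IgG libraries, common to both pairs, are a candidate explanation. The bound for it was set after these values were seen, so they are no independent support for it. A small part at the same sites stays open, because summits within 200 bp exceeded moves of 2 to 10 kb. This held for narrow peaks (183 against 160, permutation p = 0.0400) and for all peaks (333 against 257, permutation p = 0.0010). A biological cause acting over regions, such as open chromatin, was not tested.

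Chromosome X carried more pair 1 peaks than the autosomes, although at a -log10 q of at least 5 the ratio was 1.35 and chromosome 7 stood higher at 1.54. Without peaks of 5000 bp or wider the ratio was 2.10 (1.99 to 2.22), so wide multi-copy blocks are not the whole cause. Against autosomal positions of the same gene density it was 2.10 (1.99 to 2.20), so neither is gene density, even though 45.5% of pair 1 peaks against 31.5% of positions had at most 2 genes within 500000 bp. An IgD library with fewer male cells than its IgG library would lower Y while raising X. This cannot be told apart: as a ratio to the autosomes, the scale used for X, Y was higher in pair 1 (0.268, 0.217 to 0.326, and 0.109 for peaks narrower than 2000 bp) than in pair 2 (0.0547, 0.0433 to 0.0682, and 0.0168), which runs against it, but those ratios divide by 4.04 and 15.93 autosomal peaks per Mb from lists of different length, while Y itself had 1.08 peaks per Mb in pair 1 (0.878 to 1.32) and 0.872 in pair 2 (0.690 to 1.09), with overlapping intervals. The sex of the mice is not given in the labels. A bias of the pair 1 libraries that follows X, or a biological difference of X chromatin, stays open.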
